A study of Mus musculus with 22 samples.

How the data were processed

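Mouse livers labelled Fah-/- were flash frozen, RNA was extracted with TRIzol, and polyadenylated mRNA was fragmented, copied to cDNA and sequenced, per the labels' protocols. The labels name 22 libraries in 3 groups, with 7 D0 livers, 8 vehicle livers and 7 YC livers, and these groups were taken from the treatment and title labels. Replicates have numbers in the labels, but nothing there says that each came from a separate animal, so p-values measure the spread between these samples, which may be partly technical.

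The authors deposited 1 table of RPKM values (reads scaled to gene length and library size) with 1 column per library and no pooling. TopHat 1.4.1, Cufflinks 1.3.0 and the mouse build mm10 are named per the submitters' processing notes. Which tool made the values, the gene annotation, the filters and whether strand was used are not given in the sources used here. Without strand, reads of overlapping and antisense genes cannot be told apart, and reads shared by near-identical copies such as the Mup, Cyp4a12 and globin genes may have been divided in ways that set their single values. The table had 18716 rows, of which 27 carried a gene symbol turned into a date and 2 names were repeated, and 17858 row names matched a symbol of the reference annotation. The table had 0 rows for mitochondrial genes. Coordinates come from the GENCODE annotation of the same build as mm10 and cover the whole gene from its first to its last annotated base.

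Library depth was recovered from the steps of low values, because a gene with few reads takes values that are whole multiples of what 1 read is worth. From 461 genes with a single annotated transcript, the steps of 79 agreed on 1 set of depths, 51200000 to 66300000 in D0 livers, 51200000 to 71900000 in vehicle livers and 50300000 to 82900000 in YC livers. Whether these count reads or fragments is not known. At a tolerance of 0.02, 273 of 1444 genes checked (18.9%) gave whole reads in all libraries, too few for a count test, so none was run. Over low genes with recovered whole reads, the closest pair of replicates, YC 1 and YC 2, differed by a mean chi-square of 4.16 per gene over 119 genes, so no library was counted as a repeat of another. No interval from counting error was computed, and precision was taken from the spread between livers.

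Genes with at least 0.5 RPKM in at least 7 libraries were kept (12537 genes). Values were taken as log2(RPKM + 0.5) and fitted with limma 3.58.1 (lmFit, then eBayes with trend and robust, statmod 1.5.0) in R 4.3.3, with all 22 libraries in 1 model of 3 groups and no covariate. P-values were two-sided and adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Fold changes are on the log2(RPKM + 0.5) scale, which understates the change of low genes, and RPKM are given as mean ± SD. The comparisons were YC minus vehicle, vehicle minus D0 and YC minus D0. Fah was tested with exact two-sided permutation tests of mean log2 values. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

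The groups, tests, gene lists and the rule for naming genes were fixed before the data were examined. For YC minus vehicle and vehicle minus D0, the rule named the 6 rising and 6 falling called genes with the largest log2 fold change among those with a mean of at least 5 RPKM in 1 of the groups compared, leaving out predicted gene symbols, the called member with the smallest adjusted p of each list, the next 2 called and up to 2 uncalled abundant members of 5 lists (hepatocyte function, biliary and progenitor, fetal liver, cell cycle, Wnt feedback), and Fah. Beyond this rule, list members were named after their values were seen where few moved, as were Prss2, Fos and the Y-linked genes, and the genes of the closing section. The 26 lists had 457 entries for 443 genes, with 14 genes in more than 1 list, and Fah in none. They covered hepatocyte function, biliary and progenitor cells, fetal liver and oncofetal genes, cell cycle, Wnt feedback targets, pericentral and periportal hepatocytes, YAP targets, tyrosine catabolism, p53 targets, NRF2 targets, the integrated stress and unfolded protein responses, stellate cells and matrix, macrophages, sinusoidal endothelium, neutrophils, lymphocytes, erythroid cells, acute phase and cytokines, sterol synthesis, fatty acid oxidation and PPAR alpha, lipogenesis, bile acid synthesis and transport, sex-biased and sex chromosome genes, pancreatic acinar cells and immediate early genes.

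Each list was tested with limma's camera, which compares its genes with all others, at a preset correlation of 0.01 between genes, adjusted over the lists, and again with a correlation estimated from the data. Limma's fry was run beside it and tests only whether a list's genes move, on balance, 1 way. Counts of called members are given over all genes and adjusted over the list alone. List scores per library are the mean over members of log2 values centred on each gene's mean over all libraries. The reversal between comparisons was measured with the vehicle livers split into disjoint sets of 4, and overlaps against D0 livers were set beside simulated unchanged groups (20 simulations). The limma step was tested on simulated data for YC minus vehicle, in which 200 of 12537 genes were changed. It recovered 36.2% of genes changed by 0.5 on the log2 scale, 80% of those changed by 1 and 100% of those changed by 2, with 10 false calls.

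Alternatives fixed in advance were pseudocounts of 0.1 and 1, no filter on low values, a mean of at least 5 RPKM, quantile normalization, median-ratio scaling, rescaling to an equal total, limma without trend or robust, array weights, only the groups compared, the replicate number as a block, and each library left out in turn. Means without 1 library and relations to Fah with Y status as a term were added after seeing the data. Others were chosen after seeing the data and are named as such. Some results for single genes are not reported here. Xist, H19 and Ighm had no row under these symbols and were not analysed here.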

Results

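RNA sequencing of polyadenylated transcripts was carried out on 22 mouse livers labelled Fah-/-, a genotype named for the loss of fumarylacetoacetate hydrolase, the last enzyme of tyrosine breakdown. The 7 livers called D0 here were taken on day 0 and carry the label of a normal liver. The other livers had received hepatocytes labelled td and were taken 28 days after withdrawal of NTBC, an inhibitor of the tyrosine catabolism enzyme Hpd that protects livers lacking Fah. Of these, 8 were from animals given vehicle and 7 from animals given an agent labelled YC. The deposited RPKM cover 18716 rows in each of the 22 libraries, with estimated depths between 50300000 and 82900000 reads or fragments. A mean of 10414 ± 237 genes (SD, n = 7) reached 1 RPKM in D0 livers, 10806 ± 335 (SD, n = 8) in vehicle livers and 11452 ± 223 (SD, n = 7) in YC livers.

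Fah itself was examined first, since the genotype label names it and its level checks the labels. Whether the transplanted hepatocytes carried an intact Fah gene is not given in the sources used here. Fah (mm10 chromosome 7, 84585159 to 84606722) had a mean of 29.4 ± 6.09 RPKM in D0 livers (SD, n = 7), 404 ± 80.2 RPKM in vehicle livers (SD, n = 8) and 185 ± 144 RPKM in YC livers (SD, n = 7). On the log2 scale Fah was 13.5-fold higher in vehicle than in D0 livers (difference 3.76, two-sided exact permutation p = 0.000311, Benjamini-Hochberg value over 3 comparisons 0.000933). It was 4.43-fold higher in YC than in D0 livers (difference 2.15, exact permutation p = 0.00233, adjusted 0.00349). It was 3.06-fold lower in YC than in vehicle livers (difference -1.61, exact permutation p = 0.00591, adjusted 0.00591). The 8 vehicle livers lay between 271 and 542 RPKM. The YC livers spread from 31.5 to 407 RPKM, and the libraries labelled YC 6 and YC 7, at 41.3 and 31.5 RPKM, were close to the D0 range of 21.1 to 38.8 RPKM. Without these 2 libraries the difference between YC and vehicle livers was -0.88 (exact permutation p = 0.0295), a setting chosen after seeing the data. The site of the disruption in the recipients' gene is not given in the sources used here, so the level in D0 livers cannot be assigned to a part of the transcript.

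**Figure D1:**
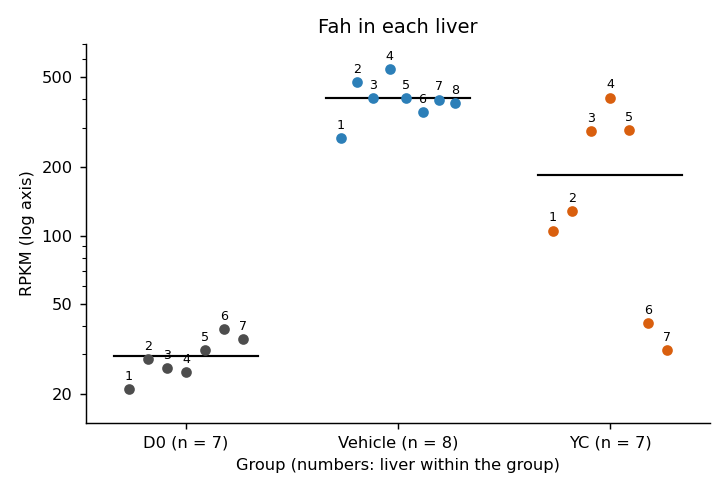
Fah RPKM (log axis) in each liver by group, with lines at the group means and numbers naming the livers within a group. The 8 vehicle livers lie between 271 and 542 RPKM, while the libraries labelled YC 6 and YC 7 lie at 41.3 and 31.5 RPKM.

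Livers given YC were compared with livers given vehicle, the comparison the design text is about, which asks whether YC stimulated growth of the transplanted hepatocytes through dedifferentiation. Transcripts of the fetal liver were among the largest differences. Afp, the fetal serum protein alpha-fetoprotein (chromosome 5, 90490737 to 90508907), averaged 2984 ± 1929 RPKM in YC livers (SD, n = 7) against 205 ± 174 RPKM in vehicle livers (SD, n = 8), a log2 fold change of 4.15 ± 0.49 (SE, limma adjusted p = 1.6e-06). Igf2, a fetal growth factor (chromosome 7, 142650766 to 142666816), averaged 103 ± 30.2 against 10.6 ± 15.3 RPKM, a log2 fold change of 4.07 ± 0.51 (limma adjusted p = 3.18e-06). Vehicle 1 held 47.3 RPKM of Igf2, and without it the vehicle mean was 5.33 ± 4.10 RPKM (SD, n = 7) and the log2 fold change 4.50. For both genes all 7 YC livers lay above the highest vehicle liver. D0 livers held 4.85 ± 1.89 RPKM of Afp (SD, n = 7). Of the 12 tested members of the fetal liver and oncofetal list, 9 rose, none fell and 3 did not pass the test, with 9 rising also when adjusted over the list alone. The list's median log2 fold change was 1.4 (adjusted p = 0.00798), with adjusted p = 0.293 with an estimated correlation. Dlk1, a surface protein of fetal hepatoblasts, was a further riser at 2.30 ± 0.31 (SE). Scd2 and Mbd1, the most abundant members not called, had values of 0.85 ± 0.45 and -0.09 ± 0.17 (SE). Scd2 was called at 1.13 when vehicle 1 was left out, at 1.2 when YC 4 was left out too and at 1.13 with array weights. List members given by name alone, without a value, were here and below named after their values were seen.

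The other genes with the largest rises were Fgfbp1 (3.69 ± 0.34, SE), which carries fibroblast growth factors, the cytochrome P450 gene Cyp2s1 (3.62 ± 0.34), the epithelial keratin gene Krt20 (3.60 ± 0.33) and the retinol-binding protein gene Rbp2 (3.43 ± 0.38). The largest falls were those of major urinary protein genes, which encode pheromone carriers secreted by the liver. Mup3 (chromosome 4, 62083476 to 62087342) averaged 62.4 ± 58.7 RPKM in YC livers against 1315 ± 877 RPKM in vehicle livers, a log2 fold change of -4.51 ± 0.51 (SE, limma adjusted p = 1.1e-06). Mup16, Mup10, Mup19 and Mup15 had log2 fold changes of -5.53 ± 1.00, -5.13 ± 1.25, -4.67 ± 0.97 and -4.41 ± 1.14 (SE). These genes are near-identical copies, so how their reads were divided is uncertain and their single values are too. Ces3a, a liver carboxylesterase gene, fell from 386 ± 156 to 67.5 ± 90.6 RPKM (log2 -4.21 ± 0.80, SE).

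**Figure D2:**
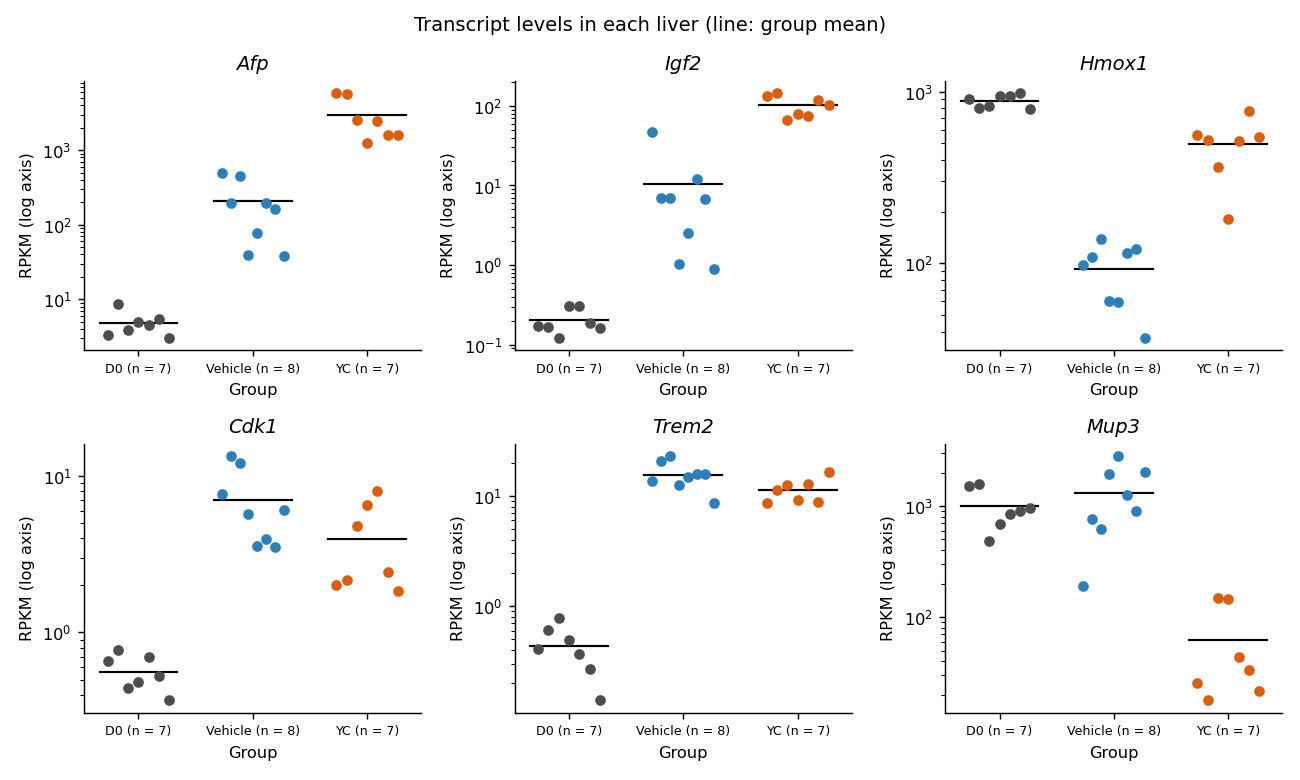
RPKM (log axes) of 6 transcripts in each D0, vehicle and YC liver, with lines at the group means. Every YC liver lies above every vehicle liver for Afp and Igf2, and below every vehicle liver for Mup3.

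In the limma fit of 12537 genes, 6357 genes differed between YC and vehicle livers at an adjusted p under 0.05. Of these, 5587 were higher and 770 lower in YC livers, so that 87.9% were higher. At least 2-fold differences were found for 1097 genes, 908 higher and 189 lower. This split depended on the scale: with median-ratio scaling 4378 genes were called, 2280 higher and 2098 lower (52.1% higher), and with quantile normalization 4366, 2257 higher and 2109 lower (51.7% higher). The median log2 fold change over all genes was 0.31 as deposited and 0.01 with median-ratio scaling, and 3050 genes were called under both. Alb, the albumin gene, took 4.58 ± 1.86% of the total RPKM in YC livers (SD, n = 7), 8.75 ± 2.51% in vehicle livers (SD, n = 8) and 7.87 ± 1.26% in D0 livers (SD, n = 7). The gene lists of this comparison are therefore given with both medians. Of 57 named gene values, 55 kept their direction and side of the threshold with median-ratio scaling.

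**Figure D3:**
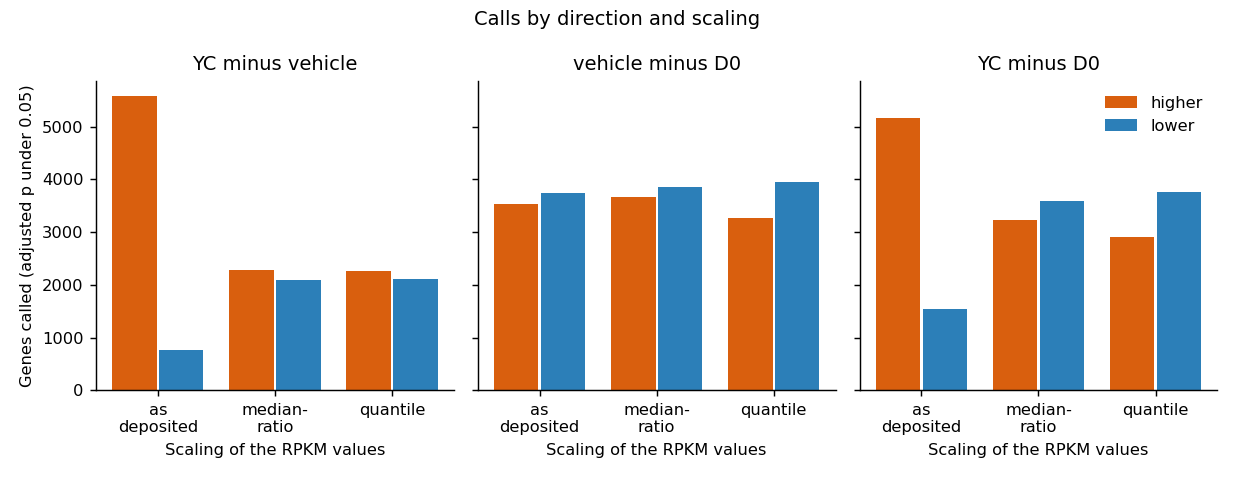
Genes called higher or lower in each comparison (bars, number of genes at an adjusted p under 0.05) with the RPKM as deposited and under 2 other scalings. Between YC and vehicle livers, 5587 higher and 770 lower genes became 2280 and 2098 with median-ratio scaling.

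Transcripts of mature hepatocyte functions were lower in YC than in vehicle livers. Of the 28 members of the hepatocyte function list, 11 fell, 1 rose and 16 did not pass the test, with 11 and 1 also when adjusted over the list alone. Cyp2c50, a drug-metabolizing cytochrome P450 gene, fell from 269 ± 62.3 to 42.3 ± 40.3 RPKM (log2 -3.21 ± 0.42, SE). Apoa2, a lipoprotein component, fell from 8440 ± 1811 to 3316 ± 572 RPKM (log2 -1.33 ± 0.17), and Ugt2b1, a glucuronosyltransferase gene, fell by 1.47 on the log2 scale. Apoa1 and Trf, the most abundant members not called, had values of -0.02 ± 0.15 and -0.31 ± 0.26 (SE). The list median was -0.48 as deposited and -0.83 with median-ratio scaling, and the list was called lower (adjusted p = 6.2e-11). It was the only one of 26 lists whose call in this comparison held with an estimated correlation, at adjusted p = 0.0373 with an estimated correlation, while 17 lists lost theirs. That call also ended without the libraries labelled YC 6 and YC 7, at adjusted p = 0.184 with an estimated correlation and a median of -0.26. The median was -0.31 with quantile normalization and -0.30 with Y-bearing YC livers alone.

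The pericentral and tyrosine pathway lists were called lower, with some YC livers inside the vehicle range, and periportal transcripts moved both ways. Among 13 pericentral hepatocyte genes 7 fell and 1 rose, the same numbers as adjusted over the list alone (median -0.94, -1.28 with median-ratio scaling, adjusted p = 2.24e-06, and adjusted p = 0.166 with an estimated correlation). Without the libraries labelled YC 6 and YC 7 the pericentral median was -0.54 (adjusted p = 3.98e-05). Cyp2c37, a pericentral cytochrome P450 gene, fell from 88.8 ± 42.8 to 21.5 ± 13.1 RPKM. The 1 riser was the Wnt target Axin2. Among 15 periportal hepatocyte genes 4 fell and 3 rose, likewise adjusted over the list alone (median -0.30, -0.65 with median-ratio scaling, adjusted p = 0.00438, and adjusted p = 0.222 with an estimated correlation). Without the libraries labelled YC 6 and YC 7 the periportal list was not called (median -0.10, adjusted p = 0.0752), and with quantile normalization its test pointed higher without passing (median -0.25, adjusted p = 0.774). With Y-bearing YC livers alone its median was -0.04 (adjusted p = 0.0161). Cdh1, the epithelial cadherin gene, was among the 3 periportal risers at 1.56 ± 0.20 (SE), with Apoa4 and Aldh1b1, while Gls2, Cyp2f2, Hsd17b13 and Alb fell. Among 7 genes of tyrosine catabolism 5 fell and none rose, and 6 fell when adjusted over the list alone (median -0.62, -0.97 with median-ratio scaling, adjusted p = 2.24e-06, and adjusted p = 0.149 with an estimated correlation). Gstz1, the enzyme acting just before Fah, fell from 413 ± 32.1 to 236 ± 58.9 RPKM (SD), and Qdpr, Pcbd1, Tat and Hpd fell with it.

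Biliary and progenitor transcripts rose in part. Cldn4, a tight junction gene of bile duct epithelium, averaged 18.8 ± 8.85 RPKM in YC livers against 2.01 ± 1.26 RPKM in vehicle livers (SD), a log2 fold change of 2.99 ± 0.32 (SE). The transcription factor gene Sox4 rose by 1.10 ± 0.18 and Bicc1 by 1.09 ± 0.22 (SE), while Spp1 and Slc4a2, with values of 0.01 ± 0.25 and 0.35 ± 0.23, were not called. Slc4a2 was called at 0.56 without the library labelled YC 7, at 0.52 without the library labelled YC 6, at 0.80 without both, at 0.77 with Y-bearing YC livers alone and at 0.69 with array weights. Bicc1 was 0.71 with quantile normalization. Of the 16 tested members of this list 7 rose and none fell, 6 when adjusted over the list alone (median 0.40, 0.09 with median-ratio scaling), and the list did not differ from the other genes (adjusted p = 0.628). Of 13 YAP targets 9 rose and none fell, likewise adjusted over the list alone (median 0.83, 0.50 with median-ratio scaling, adjusted p = 0.0347, and adjusted p = 0.51 with an estimated correlation), with Crim1 at 1.35 ± 0.18 (SE). The YAP list was not called without the libraries labelled YC 6 and YC 7 (adjusted p = 0.0555), with values rescaled to an equal total (adjusted p = 0.0632) or among genes with a mean of at least 5 RPKM (adjusted p = 0.0716). Of 11 Wnt feedback targets 6 rose and none fell, likewise adjusted over the list alone (median 0.74, 0.40 with median-ratio scaling, adjusted p = 0.628). Among them the growth regulator Myc rose by 1.10 ± 0.18, Tbx3 by 1.18 ± 0.27 and the receptor ligase gene Znrf3 by 0.79 ± 0.13 (SE), while Notum at -0.33 ± 0.38 and Tcf7 at -0.04 ± 0.17 were not called. With quantile normalization Myc was 0.71, Znrf3 0.46 and Tcf7 called at -0.45, and Znrf3 was 0.52 with median-ratio scaling.

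Cell cycle transcripts moved both ways. Mcm2 and Mcm6, subunits of the helicase that opens DNA for replication, rose by 1.33 ± 0.19 and 0.97 ± 0.21, and Ccne1, the cyclin of entry into DNA synthesis, by 1.03 ± 0.21 (SE). The other risers were Pcna, Mcm4, Mcm7, E2f1 and the mitotic genes Aurka and Bub1b, while the mitotic genes Cdk1, Ccnb1 and Cenpa fell. With median-ratio scaling 3 of the 28 tested members rose and 7 fell. As deposited 9 rose and 3 fell, 6 and 2 when adjusted over the list alone. The median was -0.09 and the mean -0.01, and the list was called lower relative to other genes (adjusted p = 0.011, and adjusted p = 0.674 with an estimated correlation). It was not called with median-ratio scaling (median -0.33, adjusted p = 0.16), with quantile normalization (median -0.43, adjusted p = 0.0904), among genes with a mean of at least 5 RPKM (median 0.41, adjusted p = 0.81) or without the libraries labelled YC 6 and YC 7 (median 0.28, adjusted p = 0.337). The median was -0.21 without vehicle 1 and YC 4 and -0.15 with Y-bearing YC livers alone, the call holding. Ube2c, an enzyme of mitotic exit, had a value of -0.64 ± 0.34, and Rrm2, a subunit of ribonucleotide reductase, 0.22 ± 0.27 (SE). Ube2c was called lower at -0.97 with median-ratio scaling, -0.96 with quantile normalization, -0.89 with array weights and -0.90 without vehicle 1 and YC 4. Mcm6 was 0.64 with median-ratio scaling and 0.62 with quantile normalization, where Ccne1 was 0.67.

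**Figure D4:**
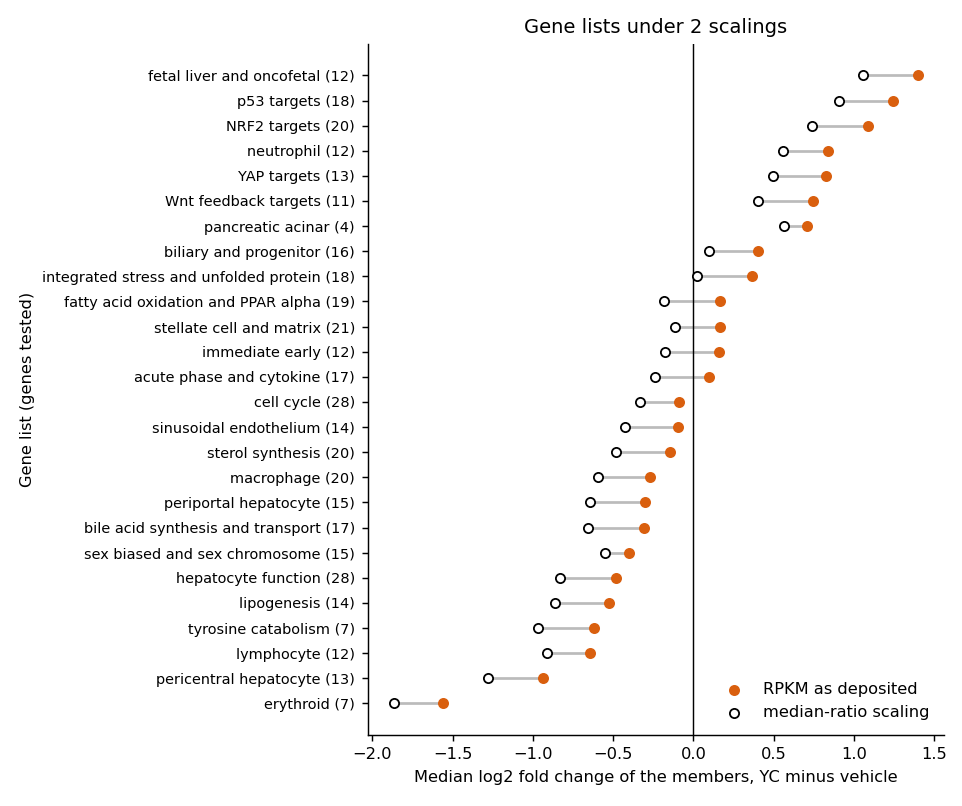
Median log2 fold change between YC and vehicle livers for the members of each of 26 gene lists (number of genes tested in parentheses), with the RPKM as deposited (filled) and with median-ratio scaling (open). The fetal list lies at 1.4 and 1.06, the hepatocyte function list at -0.48 and -0.83.

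Targets of p53 and of NRF2 were higher in YC than in vehicle livers. Of 18 p53 targets 16 rose and none fell, likewise adjusted over the list alone (median 1.24, 0.91 with median-ratio scaling, adjusted p = 0.000348, and adjusted p = 0.255 with an estimated correlation). Zmat3, a p53-induced RNA-binding protein gene, averaged 5.12 ± 1.74 RPKM in YC livers and 1.41 ± 0.34 RPKM in vehicle livers (SD). Of 20 NRF2 targets, which encode antioxidant and detoxifying enzymes, 18 rose and none fell, likewise adjusted over the list alone (median 1.09, 0.74 with median-ratio scaling, adjusted p = 0.00107, and adjusted p = 0.461 with an estimated correlation). Hmox1, heme oxygenase, averaged 494 ± 184 RPKM in YC livers and 92.3 ± 35.9 RPKM in vehicle livers (SD), a log2 fold change of 2.42 ± 0.27 (SE). Of 18 genes of the integrated stress and unfolded protein list 7 rose and 1 (Herpud1) fell, likewise adjusted over the list alone (median 0.37, 0.02 with median-ratio scaling, adjusted p = 0.875). Psat1, an enzyme of serine synthesis, was its clearest riser at 3.02 ± 0.34 (SE, 44.3 ± 22.2 against 4.62 ± 2.09 RPKM, SD). Of 12 immediate early genes 4 rose and none fell, likewise adjusted over the list alone (median 0.16, -0.18 with median-ratio scaling), with the test pointing lower and not past its threshold (adjusted p = 0.492). Ier3 rose by 1.36 ± 0.22 (SE), and Atf3, Klf6 and Btg2 rose with it.

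Markers of blood-borne and other liver cells differed in direction. Of 12 neutrophil genes 6 rose and none fell, 7 when adjusted over the list alone (median 0.84, adjusted p = 0.206), and the list was called with median-ratio scaling (median 0.56, adjusted p = 0.0286) and with quantile normalization (median 0.57, adjusted p = 0.048). Mpo, myeloperoxidase, averaged 6.1 ± 4.52 RPKM in YC livers and 0.646 ± 0.46 RPKM in vehicle livers (SD). Of 12 lymphocyte genes 6 fell and none rose, 5 when adjusted over the list alone (median -0.64, -0.91 with median-ratio scaling, adjusted p = 2.24e-06, and adjusted p = 0.185 with an estimated correlation), with the T cell receptor component Cd3d at -1.10 ± 0.24 (SE). Of 20 macrophage genes 3 rose and 3 fell, likewise adjusted over the list alone (median -0.27, -0.60 with median-ratio scaling, adjusted p = 0.000431, and adjusted p = 0.293 with an estimated correlation). The macrophage median was -0.46 without the libraries labelled YC 6 and YC 7. The risers were Cd14, a receptor for bacterial lipopolysaccharide (1.43 ± 0.31, SE), Cx3cr1 and Itgam, and those that fell were the complement genes C1qa, C1qb and C1qc. Of 14 genes of sinusoidal endothelium 1 rose and 2 fell, none and 1 when adjusted over the list alone (median -0.10, -0.43 with median-ratio scaling, adjusted p = 0.00296, and adjusted p = 0.288 with an estimated correlation), with Dnase1l3 at -0.69 ± 0.18 (SE) and Clec4g among those that fell and Lyve1 the riser. The endothelial median was -0.06 without the libraries labelled YC 6 and YC 7 and -0.01 with Y-bearing YC livers alone, the call holding. Of 21 genes of stellate cells and matrix 5 rose and none fell, likewise adjusted over the list alone. Their median was 0.16, or -0.11 with median-ratio scaling, and the test pointed lower without passing (adjusted p = 0.127). Loxl2, a collagen cross-linking enzyme, rose by 1.15 ± 0.22 (SE), and the other risers were Pdgfrb, Postn, Lrat and Reln. Of 7 erythroid genes 2 fell and 1 rose, likewise adjusted over the list alone (median -1.56, adjusted p = 0.00107, and adjusted p = 0.222 with an estimated correlation). The erythroid call was lost with median-ratio scaling (median -1.87, adjusted p = 0.0545) and with quantile normalization (median -1.75, adjusted p = 0.067). YC 6 and YC 7 had the lowest erythroid scores of the YC livers, -1.28 and -2.67, and without them the median was -0.56 (adjusted p = 0.0296). With no filter on low values it was -0.20 (adjusted p = 0.00491). Alas2, which starts heme synthesis in red cell precursors, fell from 19.3 ± 8.87 to 4.56 ± 3.05 RPKM (SD), Hba-a2 fell too, and Tfrc rose.

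Pancreatic acinar transcripts stood apart in 2 libraries, vehicle 1 and YC 4, where the trypsinogen gene Prss2 reached 65.3 and 134.8 RPKM against at most 0.409 RPKM in any other library. Of the 4 tested acinar genes 1 rose, Cela1 at 1.10 ± 0.29 (SE), likewise adjusted over the list alone (median 0.71, 0.56 with median-ratio scaling). The list test pointed lower without passing (adjusted p = 0.852). Without these 2 libraries 7311 genes differed between YC and vehicle livers, without YC 6 and YC 7 6432, settings chosen after seeing the data. Cela1 was 0.67 with Y-bearing YC livers alone.

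Metabolic lists were mixed. Of 14 lipogenesis genes 6 fell and 2 rose, likewise adjusted over the list alone (median -0.53, -0.86 with median-ratio scaling, adjusted p = 3.89e-05, and adjusted p = 0.246 with an estimated correlation). Without the libraries labelled YC 6 and YC 7 the lipogenesis median was -0.21 (adjusted p = 0.00918). The lipogenesis scores of YC 3, YC 4 and YC 5 were 0.204, 0.249 and 0.589, inside the vehicle range of -0.235 to 0.798, and those of the other YC livers lay between -1.44 and -0.847. Scd1, a fatty acid desaturase, fell from 1199 ± 521 to 252 ± 244 RPKM (SD), while Gpam and Me1 rose. Of 20 sterol synthesis genes 2 rose and 2 fell, 1 and none when adjusted over the list alone (median -0.15, adjusted p = 0.00348, and adjusted p = 0.619 with an estimated correlation). The genes that fell were Sc5d and Nsdhl. The sterol call was lost with median-ratio scaling (median -0.48, adjusted p = 0.0658), with quantile normalization (median -0.37, adjusted p = 0.275), with array weights (median 0.11, adjusted p = 0.151) and without the libraries labelled YC 6 and YC 7 (median 0.25, adjusted p = 0.706), and the median was -0.08 without vehicle 1 and YC 4 and -0.05 with Y-bearing YC livers alone. Of 17 bile acid genes 5 fell and 4 rose, likewise adjusted over the list alone (median -0.31, adjusted p = 0.00296, and adjusted p = 0.185 with an estimated correlation), and the call was lost with median-ratio scaling (median -0.66, adjusted p = 0.0555) and with quantile normalization (median -0.36, adjusted p = 0.233). The bile acid median was -0.17 without the libraries labelled YC 6 and YC 7 (adjusted p = 0.024) and -0.19 among genes with a mean of at least 5 RPKM (adjusted p = 0.0491). Abcc2, a canalicular export pump, rose from 47.4 ± 20.9 to 151 ± 44.3 RPKM (SD), as did Abcc3, Abcc4 and Cyp8b1, while Slc10a1, Slc10a2, Abcb11, Baat and Slc27a5 fell. Of 19 genes of fatty acid oxidation 6 rose and 1 fell, likewise adjusted over the list alone. Their median was 0.17, or -0.18 with median-ratio scaling, and the test pointed lower without passing (adjusted p = 0.317). Vnn1, a PPAR alpha target, rose by 1.99 ± 0.27 (SE), and the 1 that fell was Fabp1. Of 17 acute phase genes 3 rose and 3 fell, 2 and 3 when adjusted over the list alone. The median was 0.10 and the mean 0.02, yet the list was called lower relative to other genes (adjusted p = 0.00645, and adjusted p = 0.311 with an estimated correlation). The acute phase call was lost with median-ratio scaling (median -0.24, adjusted p = 0.119), with quantile normalization (median -0.17, adjusted p = 0.593), with array weights (median 0.51, adjusted p = 0.165), without the libraries labelled YC 6 and YC 7 (median 0.46, adjusted p = 0.406) and with Y-bearing YC livers alone (median 0.57, adjusted p = 0.421). Lcn2, lipocalin 2, rose from 80.5 ± 81.5 (53.1 ± 26.9 without vehicle 1) to 345 ± 166 RPKM (SD), as did Fgb and Socs3, while Hpx, Crp and Cxcl10 fell.

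Transcripts of the Y chromosome divided the livers. The summed RPKM of Ddx3y, Eif2s3y, Kdm5d and Uty was 0 to 0.05 in D0 livers, 5.55 to 35.6 in vehicle livers, 17.4 to 31.9 in YC 1, YC 2 and YC 3, and 0 in YC 4 to YC 7. With Y-bearing YC livers alone, chosen after seeing the data, 6160 genes differed from vehicle livers, of which 5273 were also called in the full comparison. Against D0 livers, which had next to none of these reads, no such comparison could be made for vehicle livers, so Y status and group cannot be told apart there. Of 15 tested genes of the sex-biased and sex chromosome list 2 rose and 4 fell between YC and vehicle livers, likewise adjusted over the list alone (median -0.40, adjusted p = 0.00106, and adjusted p = 0.149 with an estimated correlation). That call was lost with median-ratio scaling (median -0.55, adjusted p = 0.0636), with quantile normalization (median -0.43, adjusted p = 0.134), among genes with a mean of at least 5 RPKM (median 0.03, adjusted p = 0.0646) and with Y-bearing YC livers alone (median 0.03, adjusted p = 0.173). Cyp2a4, a female-biased cytochrome P450 gene, rose by 1.28 ± 0.27 (SE), as did Cyp2d9, while Ddx3y, Kdm5d, Mup20 and Cyp2b13 fell.

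Fah differed between YC and vehicle livers, so the day 28 livers were also compared with log2 Fah as a covariate, a setting chosen after seeing the data. This called 3775 genes. Its slopes rest mostly on YC livers, where Fah varied more. Vehicle livers did not show them for several lists, so those medians and calls extrapolate. The hepatocyte function list kept its call with a preset correlation, at a median of -0.17 (adjusted p = 0.000174, and adjusted p = 0.604 with an estimated correlation). The pericentral (median -0.15, adjusted p = 0.0346) and tyrosine lists (-0.22, adjusted p = 0.0148) kept theirs with medians much closer to 0, at adjusted p = 0.826 and 0.685 with an estimated correlation. The p53 (0.89), macrophage (-0.53), lymphocyte (-0.63) and sex-biased lists (-0.37) also kept theirs, at adjusted p = 0.799 for p53 and 0.685 for the others with an estimated correlation. The calls of 11 other lists ended. These were the fetal (median 1.03, adjusted p = 0.161), YAP (0.76, adjusted p = 0.144), NRF2 (0.47, adjusted p = 0.407), endothelial (-0.04, adjusted p = 0.0893), acute phase (0.43, adjusted p = 0.485) and bile acid lists (-0.03, adjusted p = 0.316). The medians of the other 5 turned positive, for cell cycle (0.57, adjusted p = 0.316), periportal (0.18, adjusted p = 0.954), erythroid (0.69, adjusted p = 0.601), sterol (0.70, adjusted p = 0.161) and lipogenesis genes (0.09, adjusted p = 0.316). Among named genes 10 calls ended, some with values about as large as before. Mup15 was -4.57, Mup10 -4.56, Cd3d -0.83, Bicc1 0.79 and Ccne1 0.70, while Scd1 was -1.58, Cd14 0.85, Dnase1l3 -0.31, Cela1 0.50 and Cyp2a4 0.44. Ces3a was -1.28, Cyp2c50 -1.82, Cyp2c37 -1.34, Alas2 -1.07, Crim1 0.89, Vnn1 1.14 and Myc 0.72, and Slc4a2 (1.06), Rrm2 (0.92) and Notum (0.90) were called.

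Vehicle livers at day 28 were compared with D0 livers, which differ in time, transplantation and NTBC withdrawal together. Pck1, Cyp4a12a, Cyp4a12b, Ly6d, Gpc3 and Afp had the largest rises among the genes the naming rule covers. Pck1, a rate-limiting enzyme of gluconeogenesis (chromosome 2, 173153048 to 173159273), averaged 927 ± 319 RPKM in vehicle livers (SD, n = 8) and 31.4 ± 18.2 RPKM in D0 livers (SD, n = 7), a log2 fold change of 4.96 ± 0.34 (SE, limma adjusted p = 1.09e-10). The male-typical genes Cyp4a12a and Cyp4a12b, which are close copies with uncertain single values, rose by 5.90 ± 0.31 and 4.44 ± 0.29, Ly6d by 5.24 ± 0.36, Gpc3, a fetal surface proteoglycan gene, by 4.91 ± 0.32, and Afp by 4.79 ± 0.49 (SE). The largest falls were those of the sulfotransferase genes Sult2a3 (-4.72 ± 0.67) and Sult3a1 (-4.09 ± 0.35), the female-typical cytochrome P450 genes Cyp2b13 (-4.56 ± 0.38) and Cyp3a44 (-4.30 ± 0.69), Mup17 (-4.27 ± 1.16), whose reads are shared with near-identical copies, and Pcp4l1 (-4.14 ± 0.37, SE). Every vehicle liver lay outside the D0 range for each of these genes except Mup17. Fah rose by 3.76 ± 0.40 (SE).

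Of 12537 genes 7278 differed, 3535 higher and 3743 lower in vehicle livers, and 1904 by at least 2-fold (1095 higher, 809 lower). The share higher was 48.6%, and 48.7% with median-ratio scaling. The median log2 fold change over all genes was 0.01 as deposited and with that scaling. No list's call in this comparison held with an estimated correlation, and 7 were lost. Without vehicle 1, D0 1 and D0 2 6946 genes differed, and without D0 1 and D0 2 6445, settings chosen after seeing the data. D0 1 and D0 2 had high immediate early transcripts, with Fos at 26.9 and 52.4 RPKM against at most 7.75 RPKM in any other library.

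Macrophage transcripts rose. Trem2, a receptor of lipid-associated macrophages, averaged 15.6 ± 4.55 RPKM in vehicle livers and 0.437 ± 0.212 RPKM in D0 livers (SD). Of 20 macrophage genes 19 rose and none fell, 20 when adjusted over the list alone (median 1.78, adjusted p = 1.18e-10, and adjusted p = 0.353 with an estimated correlation). Of 12 neutrophil genes 11 rose and none fell, 12 when adjusted over the list alone (median 1.49, adjusted p = 0.000638), and of 21 stellate cell and matrix genes 16 rose and 1 (Lrat) fell, 17 and 1 when adjusted over the list alone (median 1.12, adjusted p = 6.51e-05). Each of these last lists stood at adjusted p = 0.553 with an estimated correlation. The neutrophil median was 2.36 with a pseudocount of 0.1 and 2.70 among genes with a mean of at least 5 RPKM. Csf3r, the receptor for a granulocyte growth factor, rose by 0.84 ± 0.14, and Mmp2, a matrix-degrading enzyme, by 2.06 ± 0.26 (SE). Of 12 lymphocyte genes 6 rose and none fell, likewise adjusted over the list alone (median 0.66, adjusted p = 0.0806), with the pan-leukocyte gene Ptprc at 0.92 ± 0.16 (SE), and it was called with no filter on low values (median 0.46, adjusted p = 0.0189). Of 14 endothelial genes 4 rose and 1 fell, likewise adjusted over the list alone (median 0.30, adjusted p = 0.275), with Vwf at 0.77 ± 0.20 (SE) beside Pecam1, Cdh5 and Dnase1l3, and Kdr the 1 that fell. Of 7 erythroid genes 5 rose (Alas2 and the globin genes Hba-a1, Hba-a2, Hbb-bs and Hbb-bt) and 1 (Tfrc, the transferrin receptor gene, at -2.44 ± 0.28, SE) fell, 5 and 2 when adjusted over the list alone (median 2.31, adjusted p = 0.422). Of 4 acinar genes only Cela1 was called, at 1.53 ± 0.29 (SE), likewise adjusted over the list alone (median 1.4, adjusted p = 0.375), and vehicle 1 held the acinar transcripts given above. Of 17 acute phase genes 8 rose and 1 fell, likewise adjusted over the list alone (median 0.65, adjusted p = 0.0615), with Lcn2 at 3.61 ± 0.39 (SE) and Orm3 the 1 that fell. The acute phase list was called among genes with a mean of at least 5 RPKM (median 0.81, adjusted p = 0.0334), with array weights (median 0.75, adjusted p = 0.0211), from these groups alone (adjusted p = 0.0124), without vehicle 1, D0 1 and D0 2 (median 0.79, adjusted p = 0.0282) and without D0 1 and D0 2 (median 0.85, adjusted p = 0.0166).

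Proliferation and ductal transcripts also rose. Of 28 cell cycle genes 25 rose and 2 (Mcm7 and Pcna) fell, likewise adjusted over the list alone (median 1.33, adjusted p = 1.9e-07, and adjusted p = 0.553 with an estimated correlation). Ube2c rose by 3.29 ± 0.34, Cdk1 by 2.67 ± 0.29 and Cdc20 by 3.06 ± 0.35, while Mcm2, at 0.27 ± 0.19, was not called (SE). Among genes with a mean of at least 5 RPKM the cell cycle median was 0.85 (adjusted p = 0.0334). Of 16 biliary and progenitor genes 11 rose and none fell, likewise adjusted over the list alone (median 1.08, adjusted p = 0.00229, and adjusted p = 0.553 with an estimated correlation). Spp1, osteopontin, rose from 35.5 ± 6.89 to 189 ± 75.9 RPKM (SD), Epcam by 1.77 ± 0.26 and Tspan8 by 2.07 ± 0.33, while Krt23 (0.10 ± 0.27) and Slc4a2 (0.09 ± 0.23, SE) were not called. Of 12 fetal genes 7 rose and 2 (Abcc4 and Cbr3) fell, likewise adjusted over the list alone (median 1.39, adjusted p = 0.0228, and adjusted p = 0.553 with an estimated correlation). With no filter on low values the fetal list was not called (median 0.17, adjusted p = 0.0857). Scd2 at -0.93 ± 0.45 and Mbd1 at 0.07 ± 0.17 (SE) were not called, and Scd2 was called at -1.22 without vehicle 1, -1.15 without vehicle 7, -1.24 without vehicle 1, D0 1 and D0 2, and -0.95 with array weights.

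Antioxidant transcripts fell. Of 20 NRF2 targets 18 fell and 2 (Slc7a11 and Taldo1) rose, likewise adjusted over the list alone (median -1.48, adjusted p = 8.57e-07, and adjusted p = 0.553 with an estimated correlation). Aox1, an aldehyde oxidase, fell from 119 ± 15.9 to 18.9 ± 4.78 RPKM (SD). Of 18 p53 targets 9 fell and 4 rose, likewise adjusted over the list alone (median -0.78, adjusted p = 0.0866), with Plk2 at -1.76 ± 0.19 (SE) and Phlda3, Fas, Psrc1 and Ckap2 the risers. The p53 list was called lower with no filter on low values (adjusted p = 0.0413) and among genes with a mean of at least 5 RPKM (median -1.15, adjusted p = 0.0491). Of 18 genes of the integrated stress and unfolded protein list 7 rose and 6 fell, likewise adjusted over the list alone (median 0.08, adjusted p = 0.958), and Asns, asparagine synthetase, rose by 3.07 ± 0.38 (SE). Of 12 immediate early genes 6 fell and 1 rose, likewise adjusted over the list alone (median -0.71, adjusted p = 0.193), with Ier2 at -1.17 ± 0.22 (SE) and Junb the riser. The immediate early scores of D0 1 and D0 2 were 1.204 and 2.021 and those of the other D0 livers -0.576 to 0.09. Without D0 1 and D0 2, chosen after seeing the data, 4 of these genes fell and 3 rose, and the median was -0.23 (adjusted p = 0.972). Of 11 Wnt feedback targets 5 fell and 1, the cyclin gene Ccnd1 (2.00 ± 0.20), rose, likewise adjusted over the list alone (median -0.56, adjusted p = 0.375). Myc fell by 1.88 and Znrf3 by 0.97 on the log2 scale, Axin2, Sp5 and Rnf43 fell too, while Notum (-0.48 ± 0.38) and Tbx3 (-0.56 ± 0.27, SE) were not called, and Tbx3 was called at -0.77 without vehicle 1, -0.67 without D0 1, -0.71 without D0 2, -0.88 without both, -1.09 without all 3, -0.68 with values rescaled to an equal total and -0.89 with array weights. Of 13 YAP targets 2 rose and 3 fell, likewise adjusted over the list alone (median -0.03, mean 0.08, adjusted p = 0.995), with Axl at 1.74 ± 0.14 (SE) and Ajuba rising and Amotl2, Lats2 and Nuak2 falling.

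Hepatocyte transcripts moved both ways. Of 28 hepatocyte function genes 6 rose and 7 fell, likewise adjusted over the list alone. The median was -0.07, the mean 0.26 and the test pointed higher without passing (adjusted p = 0.828). Apoa1 rose by 1.17 ± 0.15 and Cyp3a11, a drug-metabolizing cytochrome P450 gene, by 1.48 ± 0.22, while Alb (0.22 ± 0.21) and Apoa2 (-0.01 ± 0.17, SE) were not called. Of 13 pericentral genes 6 rose and 2 fell, likewise adjusted over the list alone, with a median of -0.16, a mean of 0.10 and a test pointing higher (adjusted p = 0.816), and Cyp2c37 fell by 2.93 and Axin2 fell too. Of 15 periportal genes 5 rose and none fell, likewise adjusted over the list alone (median 0.25, adjusted p = 0.0866), the risers being Ass1, Pck1, Sds, Cdh1 and Apoa4. The periportal list was called among genes with a mean of at least 5 RPKM (adjusted p = 0.0491), with array weights (adjusted p = 0.0476), without vehicle 1, D0 1 and D0 2 (adjusted p = 0.0267) and without D0 1 and D0 2 (adjusted p = 0.0494). Of 7 tyrosine catabolism genes 2 rose and none fell, likewise adjusted over the list alone (median 0.32, adjusted p = 0.375), with Tat, the tyrosine aminotransferase gene, at 1.62 ± 0.26 (SE) beside Pcbd1. Of 17 bile acid genes 6 rose and 4 fell, likewise adjusted over the list alone, with a median of -0.15, a mean of 0.25 and a test pointing higher (adjusted p = 0.864), and the bile acid transporter gene Slc10a2 rose by 3.01 ± 0.31 (SE) while Cyp7b1, Abcc2, Abcc3 and Abcc4 fell. Of 20 sterol synthesis genes 5 rose and 2 fell, 5 and 1 when adjusted over the list alone (median 0.09, adjusted p = 0.695), with Fdps at 1.61 ± 0.44 (SE) beside Mvd, Mvk, Fdft1 and Sc5d. Of 19 genes of fatty acid oxidation 5 rose and 3 fell, 4 and 3 when adjusted over the list alone, with a median of -0.03, a mean of 0.14 and a test pointing higher (adjusted p = 0.695), and Cyp4a31 rose by 1.91 ± 0.24 (SE) with Cpt1a, Fabp1 and Acadvl among the risers and Cyp4a14 and Vnn1 among those that fell. Of 14 lipogenesis genes 3 rose and 3 fell, likewise adjusted over the list alone, with a median of 0.07, a mean of -0.04 and a test pointing lower (adjusted p = 0.864), with Acacb, Elovl5 and Pklr rising and Gpam and Mlxipl falling beside Me1, which fell by 1.4. Of 15 sex-biased and sex chromosome genes 7 rose and 7 fell, likewise adjusted over the list alone, with a median of -0.36, a mean of -0.04 and a test pointing higher (adjusted p = 0.995).

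YC livers were compared with D0 livers by counts and lists. Of 12537 genes 6699 differed, 5162 higher and 1537 lower (77.1% higher), and 2157 by at least 2-fold (1858 higher, 299 lower). With median-ratio scaling 6825 differed, 3238 higher and 3587 lower (47.4% higher), and with quantile normalization 43.7% of the calls were higher. The median over all genes was 0.25 as deposited and -0.05 with median-ratio scaling. Without the libraries labelled YC 6 and YC 7 7072 genes differed, with YC livers lacking Y-linked reads alone 5323 and without D0 1 and D0 2 5778, settings chosen after seeing the data. The fetal list (8 of 12 rose, none fell, median 2.81, adjusted p = 0.000521), the neutrophil list (12 of 12 rose, median 3.15, adjusted p = 8.58e-05), the macrophage list (19 of 20 rose, median 1.59, adjusted p = 1.87e-06), the cell cycle list (25 of 28 rose, none fell, median 1.41, adjusted p = 8.58e-05), the stellate cell and matrix list (17 of 21 rose, none fell, median 1.24, adjusted p = 0.00101) and the biliary and progenitor list (14 of 16 rose, Onecut2 fell, median 1.64, adjusted p = 0.000778) were called higher. The NRF2 list (Slc7a11 and Taldo1 of 20 rose, 10 fell, median -0.61, adjusted p = 8.58e-05), the hepatocyte function list (Apoa1, Pck1 and Gys2 of 28 rose, 11 fell, median -0.18, adjusted p = 8.94e-05), the lipogenesis list (7 of 14 fell, none rose, median -0.79, adjusted p = 0.000368), the pericentral list (Glul, Lect2, Rhbg and Cyp7a1 of 13 rose, Cyp2e1, Cyp1a2, Slc1a2, Cyp2c37 and Rgn fell, median -0.03, mean -0.72, adjusted p = 0.011) and the tyrosine catabolism list (3 of 7 fell, Qdpr and Gstz1 among them, none rose, median -0.17, adjusted p = 0.0377) were called lower. None of these 11 calls held with an estimated correlation, where adjusted p = 0.435 with an estimated correlation for the fetal, macrophage and hepatocyte function lists and adjusted p = 0.472 with an estimated correlation for the others. The pericentral and tyrosine calls were lost with median-ratio scaling (adjusted p = 0.111 and 0.0897), with quantile normalization (adjusted p = 0.328 and 0.38) and without the libraries labelled YC 6 and YC 7 (adjusted p = 0.0841 and 0.137). The tyrosine call was also lost among genes with a mean of at least 5 RPKM (adjusted p = 0.0595) and with YC livers lacking Y-linked reads alone (adjusted p = 0.12). Without the libraries labelled YC 6 and YC 7 the medians of the lipogenesis and NRF2 lists were -0.33 and -1.02, with YC livers lacking Y-linked reads alone those of the hepatocyte function and pericentral lists were -0.45 and -0.07, and without D0 1 and D0 2 those of the pericentral and tyrosine lists were -0.11 and -0.26. With no filter on low values the fetal median was 0.48. These calls held. Quantile normalization further ended the hepatocyte function (adjusted p = 0.219) and NRF2 calls (adjusted p = 0.0814). Adjusted over the list alone these counts were the same except for the cell cycle list, where 26 rose.

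The other 15 lists were not called against D0 livers. They included the YAP targets (8 of 13 rose, none fell, median 0.66, adjusted p = 0.0919), the p53 targets (8 of 18 rose, Gdf15 fell, median 0.42, adjusted p = 0.586), the acute phase list (8 of 17 rose, Orm3 and Crp fell, median 0.57, adjusted p = 0.849), fatty acid oxidation (8 of 19 rose, 2 fell, Cyp4a14 among them, median 0.25, adjusted p = 0.983) and the integrated stress list (6 of 18 rose, Atf4, Ddit3 and Hspa5 fell, median 0.25, adjusted p = 0.849), the last with a test pointing lower. The bile acid list (6 of 17 rose, Cyp7b1, Slc10a1, Abcb11, Baat and Slc27a5 fell, median -0.23, mean 0.19, adjusted p = 0.0958) and the sex-biased list (7 of 15 rose, 6 fell, median 0.70, mean -0.35, adjusted p = 0.0652) were mixed, both with tests pointing lower. The periportal list (Pck1, Sds, Cdh1, Apoa4 and Aldh1b1 of 15 rose, Cyp2f2, Hsd17b13 and Alb fell, median 0.19, adjusted p = 0.971), the endothelial list (Lyve1, Cdh5 and Vwf of 14 rose, Kdr fell, median 0.17, adjusted p = 0.586) and the sterol list (Mvk and Fdft1 of 20 rose, 3 fell, Insig1 and Stard4 among them, median 0.18, adjusted p = 0.235) had positive medians and tests pointing lower. So did the erythroid list (none of 7 rose, Klf1 and Tfrc fell, median 0.71, adjusted p = 0.216). The Wnt list (Ccnd1 of 11 rose, Myc fell, median -0.02, mean 0.13, adjusted p = 0.302), the lymphocyte list (Ptprc of 12 rose, 1 fell, median -0.07, mean 0.01, adjusted p = 0.216), the immediate early list (Junb and Ier3 of 12 rose, Jun, Egr1, Ier2 and Zfp36 fell, median -0.37, adjusted p = 0.0546) and the acinar list (Cela1 of 4 rose, median 1.92, adjusted p = 0.449) completed the set. Without D0 1 and D0 2, which had high immediate early scores, 4 immediate early genes rose (Junb, Ier3, Dusp1 and Btg2) and 1 fell (Ier2). The median was then 0.45 and the test pointed lower (adjusted p = 0.853). Adjusted over the list alone the counts differed for the endothelial list (2 rose), the periportal list (4 fell), the bile acid list (6 fell), the lymphocyte list (none fell) and the sterol list (none rose or fell). With median-ratio scaling the medians of the periportal (-0.16), integrated stress (-0.10), endothelial (-0.16), fatty acid oxidation (-0.08) and sterol lists (-0.16) were negative. Called under other settings were the YAP targets among genes with a mean of at least 5 RPKM (adjusted p = 0.0395), with array weights (adjusted p = 0.0339) and without D0 1 and D0 2 (adjusted p = 0.0258), the lymphocyte list with array weights (adjusted p = 0.038), the bile acid list among genes with a mean of at least 5 RPKM (adjusted p = 0.0333) and the immediate early list with values rescaled to an equal total (adjusted p = 0.0479). The sex-biased list was called with no filter on low values (adjusted p = 0.0374), from these groups alone (adjusted p = 0.0407) and with YC livers lacking Y-linked reads alone (adjusted p = 0.0124).

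The direction of YC livers was then set against the difference between vehicle and D0 livers. Of 7278 genes that differed between vehicle and D0 livers, 3941 also differed between YC and vehicle livers, 3027 in the opposite direction and 914 in the same direction. As these comparisons share vehicle livers, these 8 livers were split into sets of 4 in all 70 ordered ways. Genes were called with 1 set against D0 livers and YC livers compared with the other. The share of genes with an opposite sign had a median of 67.3% (range 58.4 to 75.5%). Simulated YC livers with no difference gave 50.1% with split vehicle livers and 55.4% without a split, where 69.3% was observed. The share was 41.2% for genes higher and 92.7% for genes lower in vehicle livers, and 64.1% and 74.6% with median-ratio scaling. As deposited, 4341 genes were called against D0 livers in both day 28 groups, 2923 higher and 1229 lower in both, where independent lists would share 1456 and 459. Opposite calls were made for 189 genes, where independent lists would share 1975. Simulated unchanged groups shared no calls, so they set no level. With the D0 livers split so that each group had its own, 2958 genes were called in both and a median of 69 of them in opposite directions (range 24 to 119 over 35 splits).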

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

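Tests of the hepatocyte list, of YC 6 and YC 7 and of the Y-linked reads were chosen only after those results were seen, while the splits of the libraries were planned. Of 100 splits, drawn from 6435 or 1716 possible ones, only the real one reached the number of genes called in each comparison. This argues against chance for these numbers. With libraries taken as independent, 1 in 100 is the smallest share this test could give. The real count was 6357 and the highest other 3664 for YC against vehicle, 7278 and 6477 for vehicle against D0, and 6699 and 4555 for YC against D0.

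The hepatocyte function list was lower in YC than in vehicle livers, with a median of -0.48 (SD over members 0.761). The tables argue against a few abundant transcripts setting the RPKM scale, since the median was -0.833 (SD over members 0.765, adjusted p = 1.51e-07) with median-ratio scaling. Markers of other cell types did not all rise alike. The neutrophil score minus the lymphocyte score differed by 1.61 between YC and vehicle livers (exact permutation p = 0.00186, Benjamini-Hochberg value 0.0112 over 6 tests, SD 0.67 with n = 7 and 0.64 with n = 8). Fewer hepatocytes and less Fah-expressing tissue in YC livers stay open. With log2 Fah as a covariate, at 1 slope for both groups, the median was -0.174 (SD over members 0.668), with a call at a preset correlation and none at an estimated one (adjusted p = 0.604). An effect of YC on hepatocytes also stays open, since Fah differed between these groups and the explanations cannot be told apart here.

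The libraries labelled YC 6 and YC 7 had Fah near the D0 livers, at a mean of 1.24 times the D0 mean. Mislabelled D0 livers are argued against, since at 2367 genes separating YC 1 to YC 5 from D0 livers, YC 7 lay on the YC side for 69.7% and YC 6 for 73.6%. The bounds written for this test, 10% and 90%, were both missed, and the yardstick used was added after these values were seen, namely that D0 livers left out in turn lay on the YC side for 0.8 to 8.7% of genes. Few or no Fah-expressing donor cells in these livers may also give such levels and cannot be told apart from an effect of YC, because no other donor marker was used here.

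Y-linked reads differed between the groups and among YC livers. A mix of Y-bearing and Y-lacking YC livers as the whole cause of the YC minus vehicle calls is argued against, since 6160 genes were called with Y-bearing livers alone, 5273 of them shared with the full comparison. Y-bearing tissue as the whole cause of the shift of sex-biased autosomal genes after day 0 is argued against too, since 8 of 10 such genes were called against D0 livers in the same direction in YC livers without Y-linked reads, the exceptions being Mup20 (0.63, adjusted p = 0.404) and Cyp3a41a (-0.91, adjusted p = 0.586). For vehicle against D0 livers, Y status and group cannot be told apart, as all vehicle livers had Y-linked reads and the D0 livers next to none.

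Single libraries lay far from the rest of their group, by a gap large against the group's range, in 31 of 351 tests of a named gene reported here or list score in a group, where chance gives about 1 in 20, or 17.6. In vehicle 1 these were Apoa2 at 4483, Pck1 at 274, Dnase1l3 at 13.3 and Vwf at 2.63 RPKM, and list scores of 0.35 for Wnt feedback targets, -0.18 for periportal hepatocytes, 1.38 for sterol synthesis and 3.46 for pancreatic acinar genes. In vehicle 8 they were Mbd1 at 26 RPKM and Sult3a1 at 2.43 RPKM. In YC 4 they were Bicc1 at 4.68, Cd14 at 7.48 and Fgfbp1 at 14.4 RPKM, with scores of -0.15 for YAP targets and 4.99 for pancreatic acinar genes. Among the other YC livers they were Mcm6 at 24.4 RPKM in YC 5, Mup19 at 1.44 RPKM in YC 6 and Sult3a1 at 0.139 RPKM in YC 3. In D0 2 they were Cd14 at 13.5, Cyp4a12a at 0.411 and Ier3 at 11.9 RPKM, with a neutrophil score of -0.68. In D0 6 they were Bicc1 at 1.96, Fgfbp1 at 0.207, Rbp2 at 0.197 and Sox4 at 1.28 RPKM. In the remaining D0 livers they were Alas2 at 5.79 and Dlk1 at 0.0344 RPKM in D0 5, Tfrc at 37.6 and Ugt2b1 at 149 RPKM in D0 3, and a lymphocyte score of -0.67 in D0 1.

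Against D0 livers, 189 genes were called in opposite directions, 174 lower in vehicle and higher in YC livers and 15 the reverse. All 189 were also called between YC and vehicle livers, which follows from the opposite calls. The split is as deposited and was not tested with median-ratio scaling.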

How the results depend on the processing

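Settings named here as chosen after seeing the data are the Fah covariate, those leaving out several libraries together and those by Y-linked reads. The number of genes called stayed within 1.5 times its reported value in all but 4 cases, and pseudocounts or dropping trend and robust ended no list's or named gene's call. Among genes with a mean of at least 5 RPKM, 3816, 4061 and 3560 genes were called for YC against vehicle, vehicle against D0 and YC against D0, where fewer genes (7279) were tested. With log2 Fah as a covariate 3775 genes were called between YC and vehicle livers, and the cause was not tested. Leaving out 1 library at a time gave 5609 (without YC 1) to 6967 (without vehicle 1) genes for YC against vehicle, 6850 to 7701 for vehicle against D0 and 6254 to 6856 for YC against D0. Array weights, which gave low weight to vehicle 1 (0.249), YC 4 (0.375), YC 6 (0.315) and YC 7 (0.220), called 8244, 8541 and 8356 genes. Calls of a list turned direction in 4 cases between YC and vehicle livers. These were the cell cycle list with fry (limma, median -0.09, adjusted p = 0.731) and with the Fah covariate (0.572, adjusted p = 0.316), the periportal list with quantile normalization (median -0.249, adjusted p = 0.774, test pointing higher) and the sterol list with the Fah covariate (0.704, adjusted p = 0.161), and the cause was not tested. Fry did not call 9 further lists that camera called between YC and vehicle livers, the lipogenesis (adjusted p = 0.17), sex-biased (0.229), erythroid (0.0994), endothelial (0.525), macrophage (0.581), periportal and bile acid (both 0.742), acute phase and sterol lists (both 0.931). It called 4 that camera did not, the integrated stress (adjusted p = 9.7e-05), biliary (0.00547), neutrophil (0.00758) and Wnt lists (0.0108), all higher. For vehicle against D0 fry added 4 calls, the periportal, lymphocyte and acute phase lists higher and the p53 list lower. For YC against D0 it added 7, the YAP, p53, integrated stress, acute phase, fatty acid oxidation, periportal and acinar lists, all higher, and lost the tyrosine list (adjusted p = 0.0903). Of 26 lists between YC and vehicle livers 19 stayed on their side of the threshold with median-ratio scaling, 18 with quantile normalization and 21 without YC 6 and YC 7. For vehicle against D0 all 26 did with both scalings. All 52 named gene values of vehicle against D0 kept their side with both scalings, 55 of 57 between YC and vehicle livers did with median-ratio scaling, and 43 of the 56 that could be tested with the Fah covariate did. The Fah differences and the reversal kept their direction under each alternative run for them. With the replicate number as a block (replicate block) 6002, 7129 and 6486 genes were called, and the lymphocyte (0.772, adjusted p = 0.0202) and acute phase lists (0.797, adjusted p = 0.0422) were called for vehicle against D0, with no other list's or named gene's call changed. Same-numbered livers did not deviate together, as 5 of 21 pairs had a correlation of deviations over 0.1 (range -0.386 to 0.227) and 2 correlated best with their own number, so they share only a number. Depth limits low transcripts, where 1 read is a large part of the value, and the tests on simulated data recovered 36.2% of changes of 0.5 between YC and vehicle livers.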

Other observations

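The tests of relations to Fah, and those of genes named here, were chosen only after the data were seen. Nqo1, an NRF2 target that encodes a quinone reductase, lay between 242 and 292 RPKM in D0 livers and between 28.3 and 83.8 RPKM in vehicle livers. In YC livers it spread from 49.4 to 414 RPKM, with 336 in YC 6 and 414 in YC 7. Ly6d, a surface protein gene of the fetal list, was highest in YC 6 and YC 7 at 1215 and 1089 RPKM, above 662.8 RPKM in YC 2, the next of all 22 livers.

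List scores were set against log2 Fah within each day 28 group, 52 relations in all with exact permutation p-values and Benjamini-Hochberg values over these relations. Among the 7 YC livers, the hepatocyte function score rose with Fah (r = 0.97, exact p = 0.00159, adjusted 0.0165, rho = 0.89, exact p = 0.0123, adjusted 0.064, r = 0.98 without the 2 livers farthest from the median of Fah). The periportal score did so as well (r = 0.99, exact p = 0.000397, adjusted 0.0103, rho = 0.96, exact p = 0.00278, adjusted 0.0418, r = 0.99 without them). For the erythroid list r was 0.97 (exact p = 0.000198, adjusted 0.0103, rho = 1.0, exact p = 0.000397, adjusted 0.0206, r = 0.96 without them). For sterol synthesis r was 0.98 (exact p = 0.00119, adjusted 0.0155, rho = 0.93, exact p = 0.00675, adjusted 0.0418, r = 0.97 without them). Bile acid genes had r = 0.97 (exact p = 0.00218, adjusted 0.0189, rho = 0.93, exact p = 0.00675, adjusted 0.0418, r = 0.95 without them). Lipogenesis genes had r = 0.93 (exact p = 0.00278, adjusted 0.0206, rho = 0.93, exact p = 0.00675, adjusted 0.0418, r = 0.88 without them). The cell cycle score had r = 0.86 (exact p = 0.0163, adjusted 0.0604, rho = 0.93, exact p = 0.00675, adjusted 0.0418, r = 0.78 without them). Other relations had p-values under 0.05 before adjustment and did not pass it. The p53 score had r = -0.80 (exact p = 0.0206, adjusted 0.0715, rho = -0.86, exact p = 0.0238, adjusted 0.103, r = -0.90 without them), the pericentral score r = 0.89 (exact p = 0.0139, adjusted 0.0604, rho = 0.86, exact p = 0.0238, adjusted 0.103, r = 0.77 without them), the acute phase score r = 0.85 (exact p = 0.0226, adjusted 0.0735, rho = 0.64, exact p = 0.139, adjusted 0.344, r = 0.90 without them) and the macrophage score r = -0.75 (exact p = 0.0494, adjusted 0.143, rho = -0.68, exact p = 0.11, adjusted 0.344, r = -0.57 without them). With Y status as a term for the relations above and permutation within the 3 YC livers with and the 4 without Y-linked reads, r was 0.97 for hepatocyte function (exact p = 0.0278), 1.0 for periportal (exact p = 0.00694, the smallest these 144 permutations gave), 0.97 for erythroid (exact p = 0.0139), 0.98 for sterol (exact p = 0.0278), 0.97 for bile acid (exact p = 0.0208), 0.96 for lipogenesis (exact p = 0.0417), 0.93 for cell cycle (exact p = 0.0556), -0.85 for p53 (exact p = 0.0208), 0.95 for pericentral (exact p = 0.00694), 0.92 for acute phase (exact p = 0.0972) and -0.74 for macrophage genes (exact p = 0.229). None of the 26 relations passed adjustment (smallest adjusted value 0.0602).

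Among the 8 vehicle livers, the hepatocyte function score showed no such relation (r = -0.01, exact p = 0.989, adjusted 0.989, rho = -0.05, exact p = 0.935, adjusted 0.972, r = -0.19 without the 2 farthest). The tyrosine catabolism score rose with Fah (r = 0.90, exact p = 0.00375, adjusted 0.0243, rho = 0.88, exact p = 0.00724, adjusted 0.0418, r = 0.90 without the 2 farthest). Among YC livers its r had the same sign without passing (r = 0.79, exact p = 0.0542, adjusted 0.148, rho = 0.71, exact p = 0.0881, adjusted 0.327, r = 0.74 without the farthest 2 there), and with Y status as a term it was 0.95 (exact p = 0.00694, adjusted 0.0602). Among vehicle livers the endothelial score had a closer rank relation (rho = 0.95, exact p = 0.00114, adjusted 0.0297, r = 0.76, exact p = 0.00995, adjusted 0.0575, r = 0.79 without the 2 farthest). For 3 lists whose scores rose with Fah among YC livers, r was negative among vehicle livers and did not pass adjustment. It was -0.83 for bile acid genes (exact p = 0.0153, adjusted 0.0604, rho = -0.62, exact p = 0.115, adjusted 0.344, r = -0.36 without the 2 farthest), -0.73 for sterol synthesis (exact p = 0.0584, adjusted 0.152, rho = -0.57, exact p = 0.151, adjusted 0.357, r = 0.12 without them) and -0.62 for lipogenesis (exact p = 0.101, adjusted 0.229, rho = -0.43, exact p = 0.299, adjusted 0.519, r = 0.20 without them). These 3 relations rest on the 2 farthest livers. The YAP, acinar and periportal scores had p-values under 0.05 for r and did not pass adjustment. Differences in r between groups were not tested.

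One hypothesis was that tissue without Fah may carry the NRF2 transcripts, which were high in D0 and low in vehicle livers. Among the YC livers the NRF2 score fell as Fah rose (r = -0.95, exact p = 0.000794, adjusted 0.0138, rho = -0.93, exact p = 0.00675, adjusted 0.0418, r = -1.0 without the 2 farthest), a value known when the bounds of the test were set. With Y status as a term r was -0.96 (exact p = 0.0139, adjusted 0.0677 over 26 relations). Among the vehicle livers r was -0.06 (exact p = 0.889, adjusted 0.963, rho = -0.14, exact p = 0.752, adjusted 0.909, r = -0.08 without the 2 farthest), where Fah varied less (SD of log2 Fah 0.29 against 1.43). The relation does not tell tissue composition from a response to YC, which was not tested.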
